A study of Drosophila melanogaster with 38 samples.

How the data were processed

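The series holds 38 libraries: 32 of the O-GlcNAc-seq time course (2 replicates for each genotype and time), 4 O-GlcNAc-seq libraries without feeding (2 of the time course and 2 of a pilot study) and 2 OGA ChIP-seq libraries. Groups and replicate numbers were taken from the descriptions in the labels. Per the labels' protocols, larvae were fixed in formaldehyde, chromatin was sonicated, azide-labelled material was coupled by a strain-promoted click reaction and purified on streptavidin, and OGA was precipitated with an antibody to MEGA5. The submitters' processing notes name SAMtools, bedtools 2.17.0 and the builds dm3 and sacCer3, without their roles. The aligner, the peak caller, its thresholds and the scaling of the columns are not given in the sources used here.

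The deposited O-GlcNAc table gives 1883 peaks with start, end and 16 columns of signal, 1 per genotype and chase time. Per the file headers, each signal column combines replicates 1 and 2. Its values are signal, not read counts of peaks: in the WT 0 h column the signal grew in proportion to peak width (Pearson's r of the logs over peaks 0.990), as coverage summed over the bases of a peak does. The WT 0 h values were all multiples of 0.5, as the mean of a pair of unscaled whole numbers would be. In the other 15 columns, 98.9 to 100% of the values were, within 1.2e-06, a sum of multiples of a pair of column-specific steps. After a random offset 0.584 to 22.1% were. A mean or sum of a pair of libraries with a separate factor each would give such values, but this was not shown. How the deposited columns were scaled is not given in the sources used here, and comparisons between columns rest on it. The steps did not fix values of single libraries uniquely, so none were recovered and the spread between replicates was not used. The deposited OGA list gives 3534 intervals without a score, 1 list for both ChIP-seq libraries. Chromosome names of both tables include the heterochromatin sequences of dm3. No column of per-sample values was left unused.

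Tests were written for values per library. Because the columns combine replicates, model fits per peak across libraries, leaving out replicates and count tests were not run. In their place, log2(signal + 1) was fitted against hours by least squares, for each peak and for the median over peaks, and the half-life is -1 divided by the slope. A half-life is apparent, since it assumes an exponential decline of the scaled signal. Standard errors are those of the fit. The genotype difference was the median over peaks of the log2 ratio of OGA-null to WT per time, and its trend over the 8 times was tested exactly over all 40320 pairings, two-sided. The same was done for the difference in median log2 share left between classes of peaks, where a factor common to a column cancels except for the pseudocount, for 6 relations (3 classes of peaks in 2 genotypes), with Benjamini-Hochberg adjustment over the 6. Separate factors for the 2 libraries of a column need not cancel there.

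Overlap used at least 1 bp. OGA peaks were shifted circularly within the span from the first to the last peak of either list on a chromosome, with 10000 shifts. Shares of peaks per sequence were compared with Fisher's exact test and Benjamini-Hochberg adjustment over 13 sequences. Medians of peaks with and without OGA were compared by permutation with 100000 resamples, or 10000 for alternatives. Clustering used 1000 uniform placements. The authors' signal served to rank peaks: the 5 highest by WT 0 h signal per base, the 5 highest of those with OGA, the 5 widest OGA peaks, and the 3 windows of 100 kb richest in each kind were named. Width classes for stratified permutation were 20 bp, up to 50 bp, up to 100 bp and wider. For correlations between columns, 0.02 was added to the signal per base. Positions are those of the deposited tables, plus 1 at the start.

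The tests, their settings, the rule for named peaks and the alternatives were fixed before the data were examined, except where an alternative or test is said to have been chosen after seeing the data. The line fits, the half-lives and the exact tests of trends over chase times were not fixed in advance either. They replaced the planned fits per library after the columns were found to combine replicates. The alternatives covered the overlap rule, stricter and merged lists, uniform placement, major arms only, chase times up to 16 h, pseudocounts of 0.1 and 10 and a filter on low signal. Planned comparisons of fed with unfed larvae, of turnover classes, of gene lists at promoters and of annotation classes were not run: unfed libraries have no column among the values analysed, no class is listed per peak, and the gene annotation at hand was of a later build than dm3.

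The scripts were tested on simulated data. Exponential declines with 20% noise per value were simulated from the 0 h signals. From the WT 0 h column, half-lives of 4, 8 and 12 h came back as medians of 4.21, 8.06 and 11.99 h over 657, 612 and 614 peaks. From the OGA-null 0 h column they came back as 4.30, 8.10 and 11.97 h over 650, 611 and 622 peaks. No scaling error of a whole column and no floor at 36 h was simulated. The overlap test called 0 of 20 lists made by circular shifts of the OGA list and 20 of 20 such lists with 40 planted overlaps. The test draws its own null from the same kind of shift, so this checks the code alone. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.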

Results

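The series measured how long the sugar O-GlcNAc stays on chromatin proteins of Drosophila melanogaster larvae, and where the enzyme that removes it binds. O-GlcNAc is a single N-acetylglucosamine that a transferase adds to serines and threonines of nuclear and cytoplasmic proteins, and OGA (O-GlcNAcase) is the hydrolase that takes it off. Larvae were fed an azide-bearing sugar, Ac4GalNAz at 150 uM, for 36 h, so that proteins modified in that time carried an azide. They were then moved to food without the sugar, the chase, and collected at 8 times: at once (0 h), every 4 h up to 24 h, and at 36 h. Labelled chromatin was coupled to biotin by click chemistry, pulled down on streptavidin and sequenced, an assay called O-GlcNAc-seq. Wild-type (WT, Oregon R) larvae and larvae lacking OGA (OGA-null) were each collected with 2 biological replicates per time, 32 libraries in all. A further 4 O-GlcNAc-seq libraries came from larvae that were not fed the sugar, and 2 ChIP-seq libraries, 1 per genotype, were made with an antibody to OGA.

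The deposited O-GlcNAc-seq values covered 1883 peaks, each with 1 value per genotype and time that combined both replicates, so the spread between replicates is unknown and every value below is the authors' combined value. The OGA list held 3534 intervals with no score. No total per library was given, so sequencing depth is unknown; in the WT 0 h column the median signal per base was 32.9, from 20.6 to 57.7 over the peaks. The unfed libraries were not analysed here, so no background stands beside the values. Peaks are named by position in the dm3 build, counted from 1, without gene annotation, because the annotation used here was of another build.

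The first comparison asked how fast the label left chromatin in WT larvae. All 1883 O-GlcNAc peaks lost signal over the chase. The median peak kept 48.0% of its 0 h signal after 4 h, 32.6% after 8 h, 16.3% after 12 h and 13.7% after 16 h. It kept 8.11% after 20 h, 3.06% after 24 h and 0.497% after 36 h, when 35 peaks were listed at 0. The peaks lost label at similar rates: the apparent half-life of single peaks, from a straight line through log2(signal + 1) against hours, had a median of 4.98 h and lay between 4.09 and 5.94 h from the 5th to the 95th percentile.

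A line through the median log2 signal of the 8 times fell by 0.197 ± 0.00915 (SE of the fit) per hour, an apparent half-life of 5.07 ± 0.235 h. The signal and time were inversely ordered at all 8 times (Pearson's r = -0.994, p = 2.48e-05, and Spearman's rho = -1, p = 4.96e-05, exact two-sided permutation tests over the time points). The error describes the scatter of 8 combined values around the line, not that of replicates.

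**Figure D1:**
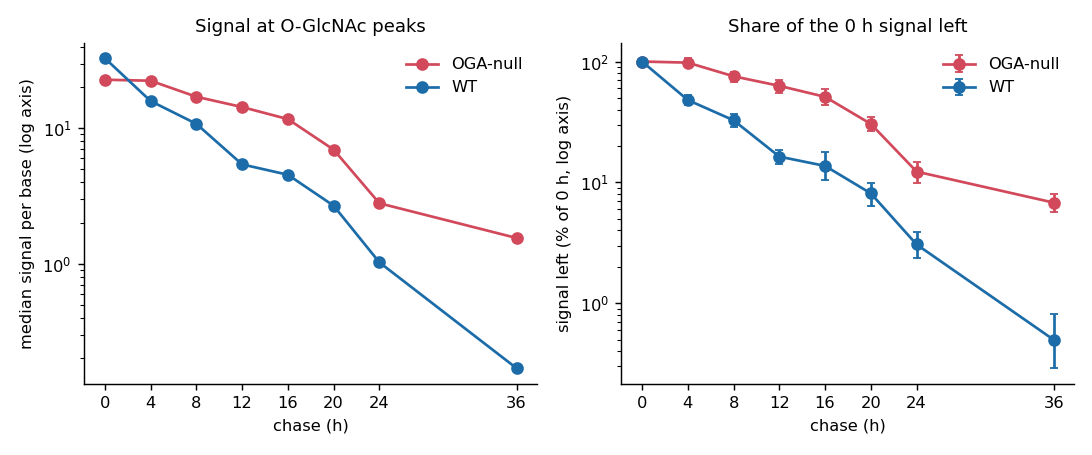
Left, median signal per base over 1883 O-GlcNAc peaks (log axis) against hours of chase in WT (blue) and OGA-null (red) larvae; right, share of each peak's own 0 h signal that was left, in percent (log axis), with points at the median and bars from the lower to the upper quartile over peaks. At 12 h the median peak kept 16.3% in WT and 62.9% in OGA-null larvae.

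The second comparison asked whether this loss needs OGA. The scaled signal fell more slowly in OGA-null larvae. Scaling that drifted with time in either genotype cannot be told apart from slower loss of label, so whether loss needs OGA stays open. The median log2 ratio of OGA-null to WT rose from -0.537 at 0 h to 1.39 at 12 h. It was 1.44 at 24 h and 2.99 at 36 h. The median peak of OGA-null larvae kept 97.9% of its 0 h signal after 4 h, when WT peaks were at 48.0%, and 825 of the 1883 OGA-null peaks were above their own 0 h value. OGA-null peaks kept 75.5% after 8 h, 62.9% after 12 h, 51.0% after 16 h, 30.5% after 20 h, 12.3% after 24 h and 6.79% after 36 h. Apparent loss was not absent without the enzyme: the signal of all 1883 peaks fell over the chase in OGA-null larvae too.

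At 0 h the OGA-null signal was the lower one, with a median per base of 22.8 against 32.9 in WT and a median ratio of OGA-null to WT of 0.689; only 3 peaks were higher in OGA-null larvae. By 4 h the median ratio was 1.40, with 1861 of 1883 peaks higher in OGA-null larvae, and by 12 h it was 2.63 with all 1883 peaks higher. From 12 to 24 h the ratio was nearly level, at 2.54 after 16 h, 2.59 after 20 h and 2.76 after 24 h. In that interval the median peak kept 18.7% of its 12 h signal in WT and 19.6% in OGA-null larvae. From 24 to 36 h the median peak kept 16.4% in WT and 54.99% in OGA-null larvae. The median ratio then reached 9.14 over the 1848 peaks with a WT value above 0. This last step rests on the WT 36 h column, which is near the floor, with a median signal per base of 0.169 and 35 peaks at 0. Across peaks that column had r from -0.11 to 0.084 with the other columns, against 0.26 to 0.65 among the rest.

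The median log2 ratio of OGA-null to WT rose by 0.0817 ± 0.0116 (SE of the fit) per hour (r = 0.944, p = 0.000174, and rho = 0.929, p = 0.00223, exact two-sided permutation tests over 8 time points). Without the 0 and 36 h points r was 0.862 (p = 0.0194, exact permutation over 6 points) and rho was 0.829 (p = 0.0583), past the threshold for r alone. The OGA-null line fell by 0.118 ± 0.0128 per hour, an apparent half-life of 8.50 ± 0.928 h, or 1.68 times that of WT. The OGA-null decline was not a straight line on the log scale: over 0 to 16 h alone the half-life came to 15.3 h, against 5.64 h in WT.

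The difference held peak by peak. All 1883 peaks had the longer half-life in OGA-null larvae, with a median ratio of 1.69 and a range of 1.34 to 2.19 from the 5th to the 95th percentile; 1874 did when the 0 h point was left out. All peaks of a column share its scaling, so these counts are no independent evidence and carry no p-value. Across peaks, which are not independent replicates, the half-lives of the genotypes had a Spearman's rho of -0.0980, which turned to 0.367 without the 36 h columns, a setting chosen after seeing the data.

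**Figure D2:**
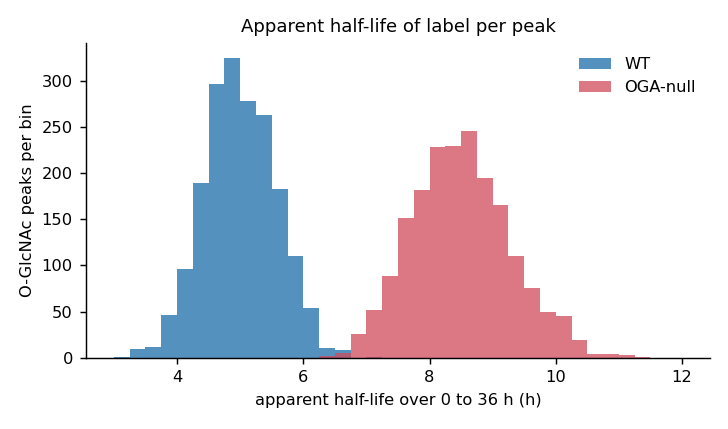
Number of O-GlcNAc peaks (vertical axis) by apparent half-life of label in hours (horizontal axis) in WT (blue) and OGA-null (red) larvae, from lines through all 8 times. The medians of the peaks are 4.98 h in WT and 8.49 h in OGA-null larvae.

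The peaks with the highest WT 0 h signal per base followed the same course. The highest, on chromosome 3R at 7394839 to 7395055, had 57.7 per base and kept 37.8% of its signal after 8 h in WT and 84.3% in OGA-null larvae. The next lay on X at 1965895 to 1966185, with 57.5 per base, and kept 32.8% after 8 h in WT against 90.1%. The peak on 3R at 26591380 to 26591737 (57.3 per base) kept 36.1% and 87.6%. On 2L, the peak at 13211944 to 13212007 (55.3 per base) kept 42.3% and 89.4%, and the peak at 12461212 to 12461403 (54.99 per base) kept 41.6% and 76.6%. None of these 5 overlapped an OGA peak, and the one at 26591380 had an OGA peak within 1 kb.

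The third comparison asked whether OGA sits where its substrate does. OGA and O-GlcNAc peaks met far more often than by chance, yet at a small part of the sites. Of 3534 OGA peaks, 85 (2.41%, Wilson 95% interval 1.95 to 2.96%) overlapped an O-GlcNAc peak by at least 1 bp, where circular shifts of the OGA list along each chromosome gave 4.42 on average (SD 2.2) and at most 15. That is 19.2 times the shifted number (p = 0.0001, one-sided permutation test with 10000 shifts, the smallest p they can give). With each OGA peak moved by only 5 to 50 kb, a test added after seeing the data, the mean was 9.30 and the excess 9.14 times. From the other side, 81 of 1883 O-GlcNAc peaks (4.30%) held an OGA peak, and 492 (26.1%) had one within 1 kb.

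OGA peaks also gathered around O-GlcNAc peaks without touching them. The median OGA peak lay 14786 bp from the nearest O-GlcNAc peak, against 45595 bp (SD 4613) after shifting (p = 0.0001, one-sided permutation test, the smallest p possible). When each OGA peak was moved by only 5 to 50 kb, which limits how far the distance can grow, it was 20235 bp (SD 475; p = 0.0001, permutation). Within 1 kb lay 477 OGA peaks, against 95.8 after shifting, and 1525 of the 3532 OGA peaks on sequences that carry both kinds (43.2%) lay within 10 kb. Both kinds of peak are narrow: O-GlcNAc peaks had a median width of 35 bp, with 679 at the minimum of 20 bp, and OGA peaks a median of 16 bp. Overlap at 1 bp therefore depends on widths set by an unstated caller. Both ChIP-seq libraries share 1 list, so peaks of the OGA-null library, which lacks the target, could not be set apart.

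**Figure D3:**
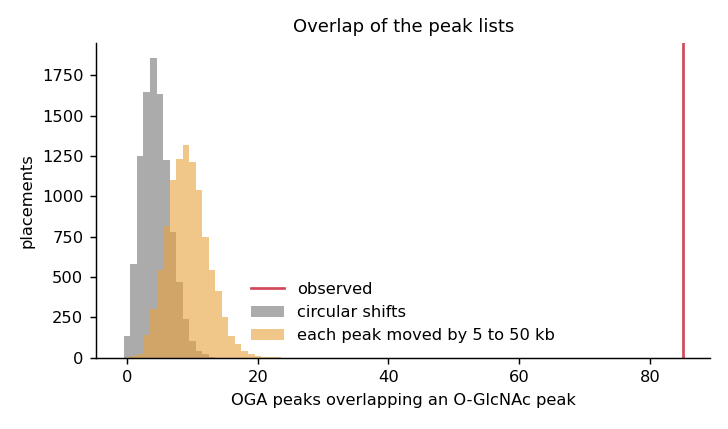
Number of random placements (vertical axis) by the number of OGA peaks that overlapped an O-GlcNAc peak (horizontal axis), for 10000 circular shifts of the OGA list (grey) and 10000 placements in which each OGA peak moved by 5 to 50 kb (orange). The red line marks the observed 85, beyond the highest of the shifts (15) and of the local moves (23).

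The O-GlcNAc peaks with OGA that had the highest WT 0 h signal were on 3L, 2L and 3R. The peak on 3L at 9369687 to 9370243, the widest in the list at 557 bp, had 52.1 per base and kept 31.0% after 8 h in WT and 88.3% in OGA-null larvae. On 2L, the peak at 19935228 to 19935361 (44.0 per base) kept 34.3% and 81.6%, and the peak at 15762673 to 15762780 (42.9 per base) kept 36.5% and 92.7%. Also on 2L, the peak at 12055894 to 12055988 (42.3 per base) kept 27.3% in WT and 100.3% in OGA-null larvae. The peak on 3R at 16078430 to 16078593 (42.0 per base) kept 37.4% and 78.3%.

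The widest OGA peaks lay away from O-GlcNAc peaks. The widest, 507 bp on X at 8189127 to 8189633, and its neighbour of 309 bp at 8188534 to 8188842 were 102 and 101 kb from the nearest O-GlcNAc peak. Those on 3L at 8722666 to 8722945 (280 bp), on 2RHet at 3179941 to 3180217 (277 bp) and on 2R at 19422968 to 19423230 (263 bp) were 36.5, 45.4 and 124 kb away.

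O-GlcNAc peaks with OGA were wider than those without, with a median of 67 bp (81 peaks) against 34 bp (1802 peaks; p = 6.00e-05, two-sided permutation test with 100000 resamples). A wider peak has more room for an overlap, and with OGA within 1 kb in place of an overlap the medians were 35 and 36 bp (p = 0.960, permutation). The WT 0 h signal per base did not differ detectably, at 33.3 with OGA and 32.8 without (p = 0.455, two-sided permutation). Peaks near each other are not independent replicates, so these p-values are too small if neighbours resemble each other.

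The fourth comparison asked where the peaks of each kind lie. Sequences of the dm3 build made of heterochromatin, named with Het, held a larger share of OGA than of O-GlcNAc peaks: 424 of 3534 (12.0%) against 81 of 1883 (4.30%). By Fisher's exact test, 5 of 13 sequences differed after Benjamini-Hochberg adjustment. In these exact tests OGA took the larger share on 2RHet (5.07% against 1.49%, adjusted p = 3.89e-11), 3LHet (3.23% against 1.12%, adjusted p = 3.69e-06), 2LHet (0.792% against 0.0531%, adjusted p = 0.000453) and 3RHet (2.69% against 1.49%, adjusted p = 0.0105). O-GlcNAc took the larger share on 3R (25.6% against 22.0%, adjusted p = 0.0105, exact test). Shares are parts of a whole, so the larger OGA share on heterochromatin sequences lowers its share elsewhere. The odds ratio of OGA over O-GlcNAc was 0.822 on 3R and 0.864 to 0.946 on 2L, 2R, 3L and X. A preference for 3R apart from the heterochromatin excess was not tested. Shares on 2L, 2R, 3L, X and chromosome 4 did not pass the threshold, with adjusted p from 0.0961 to 0.574, nor did XHet, YHet and M, which held few peaks. With peaks closer than 500 bp merged first, 3 sequences passed. The exact test takes peaks as independent draws, but peaks of both kinds lay in clusters, so these p-values are too small. Peaks of the OGA-null ChIP-seq library could not be set apart here either.

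Peaks of both kinds lay in clusters. An O-GlcNAc neighbour within 10 kb was found for 1231 of 1883 O-GlcNAc peaks (65.4%), against 517 after uniform placement, and an OGA neighbour for 2515 of 3534 OGA peaks (71.2%), against 1606 (p = 0.001 for both, one-sided permutation tests, the smallest p that 1000 placements can give). Within 50 kb 1645 O-GlcNAc peaks had a neighbour, against 1481 after uniform placement (p = 0.001, permutation), and 3300 OGA peaks, against 3296 (SD 14.1, p = 0.406, permutation). Of windows of 100 kb, the richest in O-GlcNAc peaks was on 3L from 4200001 to 4300000, with 23 O-GlcNAc and 30 OGA peaks. It was followed by 3R from 19800001 to 19900000 (21 and 19) and 3L from 5700001 to 5800000 (19 and 16). The windows richest in OGA peaks were on 3L from 4800001 to 4900000 (35 OGA and 14 O-GlcNAc peaks), 3R from 11800001 to 11900000 (34 and 10) and 3L from 8700001 to 8800000 (33 and 1).

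The apparent loss of label differed by region within each genotype, a comparison chosen after seeing the data. For heterochromatin, slower turnover and mapping to repeats cannot be told apart, and the X trend in OGA-null larvae did not pass in every setting. The shares below are set against other peaks of the same columns, so a factor common to a column leaves their ratio alone. Separate factors for the 2 libraries of a column, which the values allow, need not cancel. The trends on log2(signal + 1) also still move with the pseudocount. The 81 peaks on heterochromatin sequences kept more of their label than the other 1802 peaks: 17.98% against 13.6% after 16 h in WT, and 60.6% against 50.6% in OGA-null larvae. After 24 h they kept 3.83% against 3.03% in WT and 15.1% against 12.1% in OGA-null larvae. These are the largest OGA-null differences, 0.26 log2 at 16 h and 0.30 at 24 h, against 0.04 at 4 h, 0.02 at 8 h, 0.08 at 12 h, 0.14 at 20 h and 0.24 at 36 h. Across peaks the OGA-null 16 and 24 h columns had a Pearson's r of log2 signal per base of 0.64 with each other, and of 0.64 and 0.62 with the WT 16 h column. The OGA-null 16 h column was about as close to the WT 4 h and 8 h columns (r = 0.63 for both). The 141 peaks on X kept less than the 1660 on 2L, 2R, 3L and 3R: 11.7% against 13.7% after 16 h in WT, and 48.9% against 50.8% in OGA-null larvae. In OGA-null larvae the X difference had the other sign at 4, 8 and 12 h, with 0.006, 0.040 and 0.006 log2.

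The log2 difference of the heterochromatin peaks grew with time in WT (r = 0.957, p = 0.000422, adjusted p = 0.00253) and in OGA-null larvae (r = 0.818, p = 0.0127, adjusted p = 0.0190, exact two-sided permutation over 8 time points, adjusted over 6 relations). That of X fell in WT (r = -0.931, p = 0.00122, adjusted p = 0.00365) and in OGA-null larvae (r = -0.868, p = 0.00570, adjusted p = 0.0114, exact permutation). By rho the OGA-null trend of X did not pass (adjusted p = 0.0551, exact permutation), nor did it by r without the 36 h point (p = 0.0571). The trend of peaks with OGA over all 8 times did not pass the threshold, with r = -0.313 (p = 0.448) in WT and r = -0.389 (p = 0.325) in OGA-null larvae (exact permutation). Without the 36 h point the WT trend of peaks with OGA passed, at -0.00703 log2 per hour (p = 0.00476, exact permutation). The 0 h difference is 0 by construction, and widths differ: the median was 20 bp for heterochromatin peaks against 37 bp for the others, and 57 bp on X against 36 bp on the autosomal arms. It was 67 bp for peaks with OGA against 34 bp for those without.

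**Figure D4:**
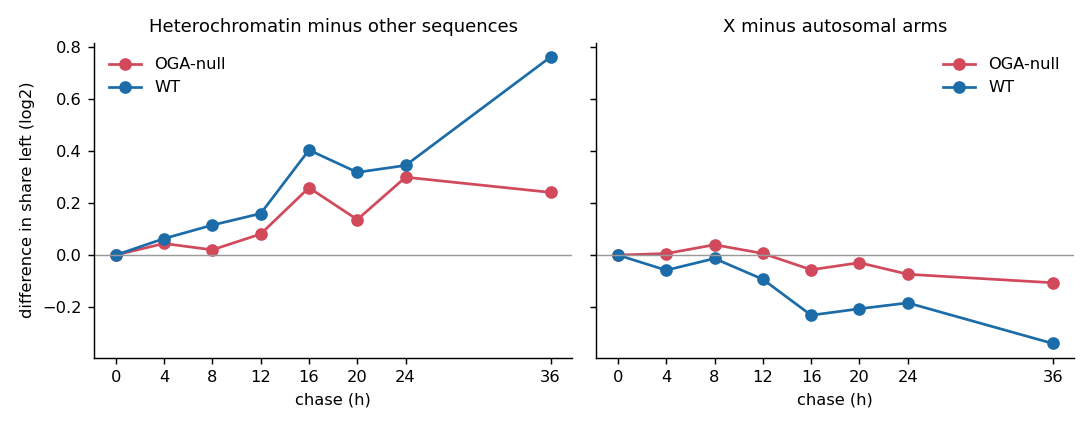
Difference in the median log2 share of 0 h signal left (vertical axis) against hours of chase (horizontal axis) in WT (blue) and OGA-null (red) larvae, for peaks on heterochromatin sequences minus all others (left) and for peaks on X minus those on 2L, 2R, 3L and 3R (right). At 16 h the heterochromatin difference is 0.40 in WT and 0.26 in OGA-null larvae, and that of X is -0.23 and -0.06.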

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

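Tests of heterochromatin, the X chromosome and OGA-bound peaks, and the tests of scaling, of the 36 h column, of pull-down without label, of mapping and of the matching on X, were chosen only after the results were seen. The local displacement of OGA peaks and the matching for width and signal were added after seeing the lists but written down before their outcome was known.

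Loss of label differed between genotypes: the median log2 ratio of OGA-null to WT rose by 0.0817 per hour. The WT 36 h column is near the floor, with 35 peaks at 0, and its signal per base over peaks had r from -0.11 to 0.084 with the other columns, against 0.26 to 0.65 among the rest. A floor there was not the whole cause, since without 36 h the ratio still rose by 0.0745 ± 0.0181 (SE) per hour (p = 0.00278, exact permutation over 7 points). Errors of scaling unrelated to time had no test apart from that of the rise itself, whose rho was 0.929 (p = 0.00223, exact permutation) and without 0 and 36 h 0.829 (p = 0.0583). Scaling that drifted with time in 1 genotype cannot be told apart from slower loss: a factor common to a column cancels, pseudocount aside, in differences between its peaks, but the heterochromatin difference grew at rates that differed between OGA-null and WT by -0.00457 ± 0.00449 (SE) log2 per hour without 36 h, and both no change and the -0.00631 of an equal slowing of all peaks lie within 2 SE. With all times the heterochromatin difference was -0.0119 ± 0.00344, beyond 2 SE of no change, and leaving out 36 h was decided after that value was seen. Within classes of width and 0 h signal it was -0.00727 ± 0.00430 with all times and -0.00323 ± 0.00616 without 36 h, both within 2 SE of no change. For X against 2L, 2R, 3L and 3R the rates differed by 0.00587 ± 0.00175 with all times and by 0.00606 ± 0.00279 without 36 h, both beyond 2 SE of no change, but by 0.00106 ± 0.00253 within classes of width and 0 h signal (0.00332 ± 0.00379 without 36 h). Separate factors for the 2 libraries of a column need not cancel in any of these differences. Slower loss for want of OGA, the biological explanation the design offers, may hold but stays open.

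The overlap of OGA with O-GlcNAc peaks could come from broad regions rich in both kinds. Moving each OGA peak by 5 to 50 kb, which stays within regions broader than the move, gave 9.30 overlaps on average and at most 23. The observed 85 were 9.14 times as many (p = 0.0001, one-sided permutation, the smallest possible). Each peak moved on its own, which breaks up clusters of OGA peaks, so this p may be too small. Shared regions shorter than 5 kb were not tested. Sites recovered without label would gain on the other peaks by about the WT loss of 0.197 log2 per hour, but the log2 share left at peaks with OGA minus the others changed by -0.00182 ± 0.00226 (SE) per hour, and by -0.00703 ± 0.00168 without 36 h. After 24 h peaks with OGA kept 2.78% and the others 3.08%. If the other peaks did lose label, this argues against such sites among peaks with OGA alone as the whole cause. That loss rests on the scaling between columns. Recovery without label at peaks of both classes would give no gain either, so it stays open. Whether open chromatin is favoured in both assays, or the antibody bound other proteins there, was not tested. Binding of OGA to its substrates thus remains a hypothesis.

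Peaks on heterochromatin sequences lost label more slowly than all others, with the difference in log2 share left growing by 0.0201 ± 0.0025 (SE) per hour in WT (r = 0.957, p = 0.000422, rho = 0.929, p = 0.00223, adjusted p = 0.00253 for r) and by 0.00823 ± 0.00237 in OGA-null larvae (r = 0.818, p = 0.0127, rho = 0.857, p = 0.0107, adjusted p = 0.0190 for r; exact permutation over 8 points). Median half-lives were 5.52 h (81 peaks) against 4.95 h (1802 peaks) in WT and 9.05 against 8.46 h in OGA-null larvae, and without 0 and 36 h r was 0.868 (p = 0.0333) and 0.835 (p = 0.05, exact). These peaks are narrower, with a median of 20 bp against 37 bp, but within classes of width and 0 h signal a WT difference of 0.431 h was left of 0.573 h (p = 0.0001, permutation, the smallest possible), which argues against width as the whole cause; without 36 h 0.528 h was left of 0.476 h (p = 0.0001). Peaks are not independent replicates, so these permutation p-values are too small if neighbours resemble each other, and they hold no spread between replicates. Between clusters of peaks, 63 on heterochromatin sequences and 958 on the arms, the WT difference was 0.587 h (p = 0.0001, permutation of clusters). That value is near the unmatched 0.573 h, so whether the matched 0.431 h holds between clusters is not shown. Reads shared between repeats could also slow the apparent loss on heterochromatin sequences. Arm peaks within 3 Mb of the centromeric ends differed from other arm peaks by 0.0461 h (p = 0.423, permutation of clusters), which neither excludes nor shows such an effect, so mapping and a slower turnover in heterochromatin cannot be told apart.

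Peaks on X lost label faster than those on 2L, 2R, 3L and 3R: the difference in log2 share left changed by -0.00951 ± 0.00153 (SE) per hour in WT (r = -0.931, p = 0.00122, rho = -0.881, p = 0.00724, adjusted p = 0.00365 for r, exact permutation). In OGA-null larvae it changed by -0.00364 ± 0.000851 per hour (r = -0.868, p = 0.00570, rho = -0.762, p = 0.0368, adjusted p = 0.0114 for r and 0.0551 for rho), so it passed by r alone, and without 36 h this no longer passed (-0.00347, p = 0.0571, exact). Without 0 and 36 h r was -0.813 (p = 0.0722, exact permutation) in WT and -0.832 (p = 0.0444) in OGA-null larvae. Within classes of width and 0 h signal the half-life on X minus the arms was -0.110 h in WT (p = 0.0337, permutation), against -0.207 h unmatched, and -0.323 h in OGA-null larvae (p = 0.0002, permutation), against -0.240 h unmatched. These 2 tests permuted single peaks, which are not independent replicates, so their p-values are too small if neighbours resemble each other.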

How the results depend on the processing

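No paired analysis was possible because each column combines replicates 1 and 2, and for the same reason no replicate was left out and no block was fitted; fits with count tools, feeding, gene list, annotation and turnover class alternatives were not run. Leaving out each time point, local moves, OGA peaks of 5 bp or more and every setting for classes of peaks were chosen after seeing the data. The slope of the genotype ratio stayed above 0 and past the threshold in all its settings, between 0.0562 (pseudocount 10) and 0.116 per hour (0 to 16 h). Over 0 to 16 h the half-life came to 5.64 h in WT and 15.3 h in OGA-null larvae, whose decline was steeper from 16 to 24 h. The median OGA-null peak kept 82.6% from 12 to 16 h, but 59.3% from 16 to 20 h and 40.3% from 20 to 24 h. With pseudocount 10, which lifts low values, the WT half-life came to 5.92 h. The overlap passed in all its settings, with 477 OGA peaks within 1 kb, 55 by midpoint and 28 in the stronger and wider parts of the lists, where the median distance was 27830 bp because fewer peaks enter. Merging left 3 sequences with different shares. With OGA within 1 kb the width difference was -1 bp (p = 0.960, permutation) and the signal difference reversed to -0.459 per base (p = 0.159), neither past the threshold. Neighbours within 2 kb numbered 767 O-GlcNAc and 1609 OGA peaks, and within 50 kb 3300 OGA peaks (p = 0.406, permutation). Over 0 to 16 h, where 5 points cannot give an exact p under 0.0167, heterochromatin in OGA-null (0.0139 per hour, p = 0.05), X in WT (-0.0125, p = 0.0667) and X in OGA-null larvae (-0.00282, p = 0.400) no longer passed, nor did X in OGA-null without 36 h (-0.00347). The difference of OGA-bound peaks passed in WT with pseudocount 10 (-0.0145 per hour) or without 36 h (-0.00703), and in OGA-null with OGA within 1 kb (-0.00208). With pseudocount 0.1 the WT value had the other sign, 0.000693 per hour (p = 0.827, exact permutation). These trends were not matched for width, and peaks that overlap OGA are wider, with a median of 67 bp against 34 bp. The half-life ratio with minus without OGA passed within 1 kb (-0.0795 log2), without 36 h (0.0618) and with both (-0.0293). The cause of the other changes was not tested. Depth per library is unknown, and its effect was not measured.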

Other observations

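The tests below were chosen after seeing the data. Median half-lives in WT were 4.95 h on 2L, 4.91 h on 2R, 5.11 h on 3L and 4.94 h on 3R, and lower, 4.76 h, on X; in OGA-null larvae they were 8.41, 8.56, 8.44, 8.49 and 8.24 h in that order. The heterochromatin sequences with more than 20 peaks were above all of these in both genotypes: 5.48 h and 9.08 h on 2RHet (28 peaks), 5.54 h and 8.91 h on 3LHet (21 peaks), and 5.57 h and 9.16 h on 3RHet (28 peaks). The slowest WT peak, chosen after its values were seen, lay on 3RHet at 2225687 to 2225706, where it overlapped an OGA peak, with 7.11 h in WT and 11.01 h in OGA-null larvae. Half-lives of single WT peaks moved with the 36 h column: the shortest, 3.11 h on X at 11698214 to 11698420, became 4.90 h without it, and that of the 3RHet peak 6.88 h. Widths were not matched here: medians were 20 to 22 bp on these heterochromatin sequences, 33 to 40 bp on 2L, 2R, 3L and 3R, and 57 bp on X. The 3 slowest WT peaks were 20 bp wide and the 3 fastest 94 to 207 bp. The pseudocount weighs more on narrow peaks, whose summed signal is lower.

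If OGA acts where it is bound, loss of label at O-GlcNAc peaks with OGA may depend more on the enzyme than elsewhere. The ratio of OGA-null to WT half-lives was 1.68 at the 81 peaks with OGA and 1.69 at the others (log2 difference -0.01, p = 0.853, permutation within width classes). Without 36 h it was 1.73 against 1.66 (log2 difference 0.0618, p = 0.0267 by permutation, adjusted p = 0.0481 over 9 tests). With OGA within 1 kb the ratio was lower, 1.63 at 492 peaks against 1.72 at 1391 (log2 difference -0.08, p = 0.0001 by permutation, the smallest possible, adjusted p = 0.0003), and -0.03 without 36 h (p = 0.0157). The direction turned with the 36 h columns for overlapping peaks, and without these columns with the definition of a bound peak, so the hypothesis was neither borne out nor excluded. Single peaks were permuted, so the p-values are too small if neighbours resemble each other.

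Across peaks, which are not independent replicates, the WT 16 h column was closer to OGA-null at 16 h (Pearson's r of log2 signal per base 0.64) and at 24 h (0.62) than to WT at 20 h (0.50) or 24 h (0.31). The WT 24 h and 20 h columns had a low r with every column, at most 0.37 and 0.51. With WT at 4 and 8 h the WT 16 h column had r of 0.53 and 0.55. Over windows of 100 kb with a peak of either kind, 540 of 960 held both, 92 O-GlcNAc peaks alone and 328 OGA peaks alone, with a Spearman's rho of 0.308 between the numbers.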
